A study of Rattus norvegicus with 38 samples.

How the data were processed

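The samples were liver tissue of Fischer (F344) and Brown Norway (BN) rats, measured on dual-channel expression arrays. Per the labels, total RNA was extracted with Tripure and reverse transcribed with a Cy3 or Cy5 label. On the lesion arrays, dysplastic nodules (week 32) or hepatocellular carcinomas (HCC, week 60) were labelled with Cy3 and normal liver of the same strain with Cy5. The normal-liver files set F344 liver against BN liver. The labels call the controls untreated and the lesions treated, and do not name the treatment. The strain field of the Cy3 channel names the opposite strain on the lesion arrays, so the strain was taken from the title and the source name. The HCC labels count the replicates as "of 8", and 7 HCC files per strain were given.

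Per the file headers, the deposited scanner files hold the intensity of each spot and of its local background as pixel medians and SDs, on a linear scale and without normalization. They also hold, per the file headers, the percent of each spot's pixels that were saturated. The other deposited fields used were the flag code, position and diameter of each spot. The deposited log2 ratios of Cy3 over Cy5, given in the scanner files and in the value table, were normalized per array by the authors with a method that is not stated. All 20500 entries of the value table matched the scanner files at 3 decimals, and 26 values were missing. The arrays held 22575 spots, 2075 of them control spots. Of the gene spots, 6185 were named through an accession and 3233 through the symbol of the spot's description, both against a table of current rat gene names (assembly GRCr8, used for names alone). A further 2924 carried a symbol that is not in that table and 8158 had none. No reference genome was at hand, so no coordinates are given. In 1 file, 16 lines ended early.

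Files were compared in pairs for shared scans. In 14 lesion files all signals were those of another file of the group times a factor of 0.94 to 0.997, and the 8 normal-liver files were scans of 4 slides. Copies and scans of one slide were averaged, which left 24 distinct files, used as 20 arrays, 4 per lesion group and 4 normal-liver slides. F344 nodule array 7 and F344 HCC array 7 hold one slide, which stands in both groups, so these 2 groups are not independent of each other and at least 1 of the 2 labels is wrong. The labels give opposite dye orientations for scans of one slide. The direction of the normal-liver ratio was therefore left open, and strain and dye could not be told apart in it.

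Signals were background corrected with normexp (offset 50) and normalized within arrays by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the data.table package, version 1.17.8. A probe was kept if its median exceeded the local background median by 2 background SDs in at least 1 channel on at least 7 of the 24 distinct files. This kept 12164 probes, with 6549 gene symbols. All spots were used whatever their flag code, since the meaning of the codes is not stated. Linear models were fitted over the 20 arrays with 1 mean per group (lmFit, eBayes, prior df 12.3), and two-sided moderated tests were adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. A lesion against normal liver was the mean log2 ratio of its 4 arrays against 0, which leaves out the spread among normal livers. HCC against nodules was the difference of the lesion means of one strain. The strain difference in an effect was the F344 effect minus the BN effect, in which a dye effect of a probe cancels. The normal-liver comparison was the mean ratio of the 4 slides against 0, reported without a direction. All ± values beside log2 changes are SEs from limma unless named SD, and n counts arrays after this averaging. The number of arrays limits the precision.

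The design fixed before the data were examined had all 38 files as separate arrays, a dye intercept and a strain column. It was replaced once the copies and rescans were found, and it is kept as an alternative. The gene lists and the rule for named genes were fixed at the same time as that design. The rule names, per comparison of a lesion with normal liver and for normal liver, the 8 largest rises and 8 largest falls with adjusted p under 0.05 that went the same way on every array. For HCC against nodules and for the strain differences it names 5 and 5. It adds the sentinels Gstp1, Ggt1, Afp, Akr7a3, Nqo1, Mat1a, Mat2a, Alb, Cps1, Cyp2e1, Cyp2c11, Ccnd1, Cdk1, Top2a, Myc and Igf2, of which Ggt1, Mat1a, Mat2a, Alb, Ccnd1 and Igf2 were not measured, and up to 4 called members per list with the largest change. The brightest probe stood for a gene, and names made of LOC or RGD numbers were passed over. Genes with another probe of opposite sign are pointed out. The sentinels Cps1 and Top2a, and Cdk1 in normal liver, were above background in Cy3 on 0 of 4 arrays of some groups, so no size is given for them.

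The 23 gene lists were preneoplastic and tumour markers, NRF2 and glutathione, cytochromes P450, urea cycle and amino acid catabolism, methionine and one-carbon metabolism, plasma proteins, gluconeogenesis and glycogen, glycolysis of non-hepatic type, lipogenesis and sterol synthesis, fatty acid oxidation, cell cycle, growth signalling and transcription factors, heat shock and ER chaperones, cytosolic ribosomal proteins, oxidative phosphorylation, MHC and interferon response, RNA quality and immediate early genes, and markers of fibroblasts and matrix, bile duct and oval cells, macrophages, lymphocytes, endothelium and red blood cells. They were tested with camera (preset correlation 0.01, and again with an estimated correlation), adjusted over 207 tests.

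Alternatives to background correction, normalization, filter, array weights, value table, replicate and print blocks, dye term, flag code, shared slides and left-out arrays were run, and their effects are given in the closing section. Print-tip loess was not run, since each file gives 1 block. A planned split of the normal-liver arrays did not apply to 4 slides. The models were tested on simulated data (100 draws, seed 7) with 4 arrays per group and variances drawn from the fitted prior. That draw was adopted after the test had failed with a criterion on a single draw and again with the probes' shrunken variances. For F344 nodules against normal liver, 29.8% of 2-fold and 96.7% of 4-fold changes were recovered, with 4.88% false calls. For F344 HCC against nodules, 5.3% and 68.1% were recovered with 4.79% false calls, and for the strain difference in nodules 5.9% and 67.4% with 5.26%. Under a simulation with the probes' shrunken variances, the false calls were 4.84%, 5.45% and 4.87%. Both simulations drew independent arrays, and left out the slide and the Cy5 image that the F344 lesion groups share. The recovery for F344 HCC against nodules therefore does not carry over to the real comparison. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.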

Results

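Gene expression was measured in liver lesions of 2 inbred rat strains, F344, known as susceptible to chemically induced liver cancer, and BN, known as resistant. The arrays measured gene spots in dual colour. The 38 files comprised 8 files of dysplastic nodules and 7 of HCC per strain, and 4 normal-liver files under each strain's name. A lesion (Cy3) was hybridized with normal liver of its strain (Cy5), so a log2 ratio above 0 is a level above normal liver. In 14 lesion files the signals were those of another file of the group times a constant, which left 4 arrays per lesion group, named here by their label numbers 1, 3, 5 and 7. The 8 normal-liver files were scans of 4 slides. Across bright gene spots (net signal over 500), the deposited log ratios correlated at 0.935 to 0.975 within a slide and 0.362 to 0.623 between slides. Among all other pairs of files r reached 0.93, so r alone does not settle a shared slide. F344 nodule array 7 and F344 HCC array 7 held one slide (r = 0.968 across bright spots, 65.2% of the Cy5 background SDs identical). One slide cannot hold both lesions, so at least 1 of these 2 labels is wrong, which one is not known, and a group of the F344 lesions has at most 3 arrays of its own stage. F344 nodule array 3 and F344 HCC array 3 shared a Cy5 image (24.2% of the Cy5 background SDs identical, r = 0.444 across bright spots). Their Cy3 signals differed, with an interquartile range of 1.226 for the log2 ratio. At least 1 of these 2 files therefore appears to pair channels of different slides. Which one is not known, and both were kept in their groups. Spots are not independent replicates.

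Per file, 11.1% to 94.4% of the gene spots were above background in Cy5 and 9.3% to 50.5% in Cy3. The group medians in Cy3 lay between 17.1% (F344 nodules) and 22.9% (F344 HCC). Each F344 lesion group had 3 arrays of an older print and 1 of a newer print, and each BN lesion group and normal liver had 1 and 3. Across probes, which are not independent replicates, the log2 ratios of 2 arrays of a group correlated with a median r of 0.25 in F344 nodules, 0.09 in BN nodules, 0.3 in F344 HCC, 0.54 in BN HCC and 0.22 in normal liver. The number of arrays limits the precision of every value.

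**Figure D1:**
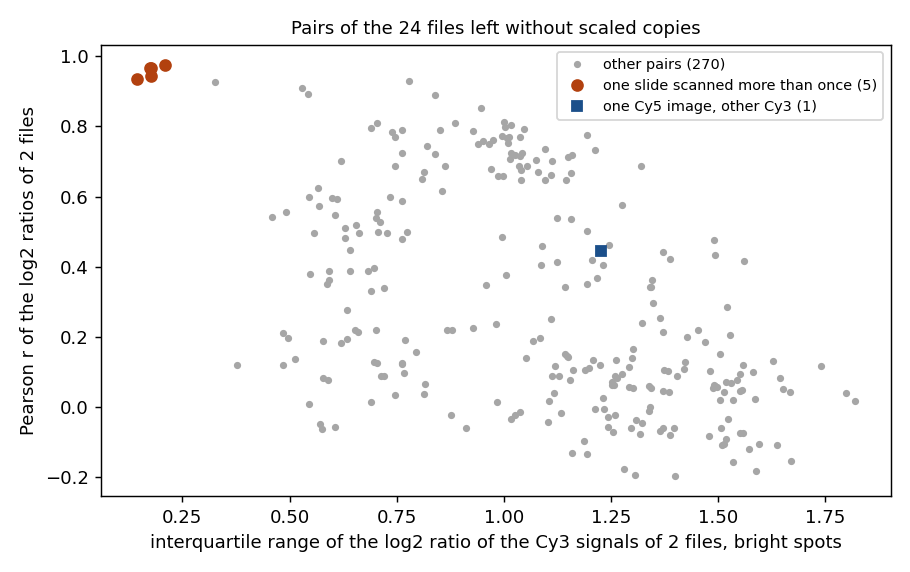
Each point is a pair of the 24 files left without scaled copies, by the interquartile range of the log2 ratio of their Cy3 signals (horizontal axis) and the Pearson r of their log2 ratios (vertical axis). Both were computed over bright gene spots. The 5 pairs that held one slide (orange circles) had interquartile ranges of 0.145 to 0.209, against 0.326 to 1.818 in the 270 other pairs (grey), and the blue square is the pair that shared only its Cy5 image.

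The nodules were set against normal liver to find which genes differ in the early lesion of each strain. In F344 nodules, Gstp1, the placental glutathione transferase used as a marker of preneoplastic rat liver, rose 57.6-fold (log2 change 5.85 ± 0.44 SE, n = 4 arrays, adjusted p = 8.76e-10). Car2 (carbonic anhydrase 2) rose 29.2-fold (4.87 ± 0.52, adjusted p = 3.62e-07), and was above background in normal liver on 1 of 4 arrays. The glutathione transferase Gsta3 rose 22.6-fold (4.5 ± 0.29, adjusted p = 3.7e-11) and the aflatoxin aldehyde reductase Akr7a3 rose by 4.17 on the log2 scale (± 0.29, adjusted p = 2.57e-10). The Gsta3 rise was smaller with the normal-liver slide mean taken off as a dye term. That term took the Gsta3 log2 change in BN nodules from 1.33 to -0.51, and the same step applies here. The oestrogen sulfotransferase Sult1e1 fell 20.3-fold (-4.35 ± 0.61, adjusted p = 2.52e-05), detected on 2 of 4 nodule arrays, and the drug-metabolizing cytochrome Cyp3a2 fell 20.1-fold (-4.33 ± 0.54, adjusted p = 4.99e-06), detected on 2 of 4. All 4 arrays showed each of these directions. Other large rises were those of the prostaglandin reductase Ptgr1 (16.2-fold), the aldehyde dehydrogenase Aldh3a1 (13.7-fold), the quinone reductase Nqo1 (13.4-fold). Pla2g7, which hydrolyses platelet-activating factor, rose 20.9-fold. Other large falls were those of Cyp3a23-3a1 (15.3-fold), the fatty acid hydroxylases Cyp4a8 (9.43-fold, detected on 1 of 4 nodule arrays) and Cyp4a3 (7.43-fold), the bile acid-CoA ligase Slc27a5 (9.38-fold, set by array 5 at -7.01, log2 change -1.97 without it), the male-specific Cyp2c11 (8.59-fold, detected on 2 of 4) and the cadherin Cdh17 (6.9-fold, detected on 1 of 4).

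By gene group, 12 of 18 preneoplastic and tumour markers rose in F344 nodules and 0 fell (12 and 0 adjusted over the list alone; list adjusted p = 4.16e-14, and adjusted p = 0.00397 with an estimated correlation). Of 25 NRF2 and glutathione genes, which protect against electrophiles, 17 rose and 0 fell (19 and 0 adjusted over the list alone; 2.22e-25, and adjusted p = 0.0111 with an estimated correlation), among them Gclm (12.8-fold) and Gstm1 (8.14-fold). Of 32 cytochromes P450, 0 rose and 18 fell (1 and 22 adjusted over the list alone; 9.83e-14, and adjusted p = 0.018 with an estimated correlation). Of 53 plasma proteins, 1 rose and 22 fell (2 and 34 adjusted over the list alone; 6.12e-13, and adjusted p = 0.0489 with an estimated correlation). Mbl2, a lectin of complement, was 4.37-fold lower, Apom 4.01-fold lower and Igfbp3, a carrier of insulin-like growth factors, 5.02-fold higher. Of 45 cytosolic ribosomal proteins, 18 rose and 0 fell (27 and 0 adjusted over the list alone; 7.81e-14, but adjusted p = 0.114 with an estimated correlation). Of 8 bile duct and oval cell markers, 3 rose and 0 fell (3 and 1 adjusted over the list alone; 0.00135, but adjusted p = 0.124 with an estimated correlation). These were Anxa1 (10.7-fold, detected in normal liver on 1 of 4 arrays), Krt19 (8.84-fold, also on 1 of 4) and Epcam (4.01-fold). Fatty acid oxidation had 1 rise and 6 falls of 30 (1 and 8 adjusted over the list alone; 0.0015, but adjusted p = 0.0782 with an estimated correlation). The acyl-CoA synthetase Acsl1 was 2.67-fold lower. Urea cycle and amino acid catabolism had 1 and 5 of 30 (2 and 7 adjusted over the list alone; 0.000532, but adjusted p = 0.127 with an estimated correlation). Lipogenesis and sterol synthesis had 1 and 4 of 30 (1 and 11 adjusted over the list alone; 0.005, but adjusted p = 0.198 with an estimated correlation). Gluconeogenesis had 1 and 2 of 15 (1 and 4 adjusted over the list alone; 0.0358, but adjusted p = 0.216 with an estimated correlation). Glycolysis had 2 and 1 of 17 (3 and 1 adjusted over the list alone; 0.0462, but adjusted p = 0.219 with an estimated correlation). The gluconeogenesis call ended without array 1 (0.071), 5 (0.0797) or 7 (0.0886) and the glycolysis call without array 1 (0.0737), 3 (0.0655) or 7 (0.0928), within ranges over all alternatives of 0.00726 to 0.216 and 0.0258 to 0.41. Methionine and one-carbon metabolism did not pass (2 and 3 of 17, adjusted p = 0.293). The growth regulator Myc rose 4.46-fold (2.16 ± 0.29, adjusted p = 1.43e-05), and Cyp2e1 fell 2.39-fold (-1.26 ± 0.32, 0.0132), a call that ended without array 5 (-1.11) or 7 (-1.0). Afp (-0.64 ± 0.4, adjusted p = 0.366, another probe of opposite sign), Cps1 (adjusted p = 0.426), Cdk1 (0.49 ± 0.27, 0.299) and Top2a (adjusted p = 0.948) did not pass.

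In total 908 probes differed between F344 nodules and normal liver, 409 higher and 499 lower. The count was 761 with the replicate numbers as a block (438 on the F344 lesion arrays alone) and 736 with print as a block. It was 99 on the 3 older-print arrays, 72 on the 1 newer-print array, and 525 without array 3 and 488 without array 5. It was 191 with scale normalization between arrays (115 higher, 76 lower; the Pla2g7 call ended, log2 3.35), 468 in the deposited values (287 and 181), and 244 with the normal-liver slide mean taken off as a dye term (140 and 104; Cdh17 at -0.05, and the lipogenesis list reversed at adjusted p = 0.808 in a range of 0.000342 to 0.866).

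In BN nodules, Gstp1 rose 14.5-fold (log2 change 3.86 ± 0.44 SE, n = 4 arrays, adjusted p = 1.61e-05) and Akr7a3 5.84-fold (2.55 ± 0.29, adjusted p = 1.61e-05), each on all 4 arrays. Wrnip1, a protein that binds the Werner helicase, was at least 2.61-fold lower (adjusted p = 0.00556) and above background on 0 of 4 nodule arrays. The other named changes were those of Gsta3 (2.52-fold higher), the glycogen precursor enzyme Ugp2 (2.2-fold higher), the respiratory chain subunit Uqcrq (at least 2.56-fold lower, above background on 0 of 4 nodule arrays), the ubiquitin ligase Herc1 (lower, adjusted p = 0.00978, likewise on 0 of 4, so no fold is given) and Zfyve9 (2.49-fold lower, another probe of opposite sign). Of the 18 preneoplastic and tumour markers 2 rose and 0 fell (5 and 0 adjusted over the list alone; list adjusted p = 2.01e-09, and adjusted p = 0.0111 with an estimated correlation). Of the 25 NRF2 and glutathione genes 1 rose and 0 fell (6 and 0 adjusted over the list alone; 2.32e-10, but adjusted p = 0.0722 with an estimated correlation). Ribosomal proteins (0 of 45 members passed; 0.00354, but adjusted p = 0.578 with an estimated correlation) and endothelial markers (0 of 16; 0.0361, but adjusted p = 0.2 with an estimated correlation) had higher lists. Both had 0 and 0 members adjusted over the list alone, and camera's direction for ribosomal proteins reversed with median centring. The ribosomal call ended without array 5 (0.0762) and the endothelial call without array 3 (0.266) or 7 (0.0722), in ranges of 7.3e-06 to 0.578 and 0.0139 to 0.967. Cytochromes P450 had 0 called members of 32 and a median of 0.02 (adjusted p = 0.265), and urea cycle genes 0 of 30 (0.644), with a test in the direction opposite to their median of -0.05. Both lists turned lower and passed with the dye term (0.0121 in a range of 0.0121 to 0.92, and 0.00122 in a range of 0.00122 to 0.969) and with the 38 separate arrays (0.0163 and 0.00133). Nqo1 (1.06 ± 0.35, adjusted p = 0.192), Cyp2c11 (0.11 ± 0.42, 0.95), Cyp2e1 (0.26 ± 0.32, 0.795), Myc (-0.12 ± 0.29, 0.907), Cdk1 (-0.3 ± 0.27, 0.687), Cps1 (adjusted p = 0.904), Top2a (adjusted p = 0.972) and Afp (0.29 ± 0.4, 0.818) did not pass.

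In BN nodules 21 probes differed from normal liver, 5 higher and 16 lower, with 1591 at an unadjusted p under 0.05. The count was 11 with the replicate numbers as a block, and 17 with print as a block. It was 1 on the 1 older-print array, 373 on the 3 newer-print arrays (38 higher, 335 lower), 6 without array 3 and 4 without array 5. It was 13 with scale normalization (2 and 11), 7 in the deposited values (3 and 4) and 15 with the dye term (10 and 5; Gsta3 at -0.51). The calls of Gsta3, Ugp2, Uqcrq and Zfyve9 ended with any 1 array left out (adjusted p from 0.0522 to 0.335), that of Wrnip1 without array 3 (adjusted p = 0.0638, in a leave-one-out range of 0.0276 to 0.0638). That of Herc1 ended without array 3 (adjusted p = 0.0585) or 5 (0.13), in a leave-one-out range of 0.0325 to 0.13, and that of Gstp1 with scale normalization (3.61).

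HCC was set against normal liver to find which genes differ in the carcinoma of each strain. In F344 HCC, Gstp1 rose 68.8-fold (log2 change 6.1 ± 0.44 SE, n = 4 arrays, adjusted p = 5.35e-10) and Gsta3 15.1-fold (3.92 ± 0.29, adjusted p = 5.35e-10). With the dye term the Gsta3 rise was smaller, by the same step as in BN nodules (log2 1.33 to -0.51). Cyp3a2 fell 44.1-fold (-5.46 ± 0.54, adjusted p = 1.22e-07, detected on 1 of 4 HCC arrays), Sult1e1 39.0-fold (-5.29 ± 0.61, adjusted p = 8.52e-07, on 1 of 4) and Cyp3a23-3a1 35.9-fold (-5.17 ± 0.48, adjusted p = 6.03e-08, on 3 of 4). Each of these went the same way on all 4 arrays. Ptgr1 (11.1-fold), Nqo1 (10.5-fold), Car2 (10.0-fold), the calcium-binding S100a6 (9.55-fold) and the tubulin Tubb6 (9.51-fold) rose as well, and so did Pla2g7 (15.4-fold). The protease inhibitor Serpina3c (11.7-fold), the fatty acid-binding Fabp1 (10.8-fold), the sulfotransferase Sult1c3 (10.6-fold, detected on 1 of 4), Cyp2c11 (12.8-fold, on 1 of 4) and Cyp4a8 (log2 -3.46, on 1 of 4) fell.

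Among gene groups in F344 HCC, 11 of 18 preneoplastic and tumour markers rose and 0 fell (13 and 0 adjusted over the list alone; list adjusted p = 2.12e-14, and adjusted p = 0.00397 with an estimated correlation). Akr7a3 was 6.77-fold and Aldh3a1 6.62-fold higher. NRF2 and glutathione genes had 16 rises and 0 falls of 25 (18 and 1 adjusted over the list alone; 6.4e-18, and adjusted p = 0.0218 with an estimated correlation). Cytochromes P450 had 1 rise and 22 falls of 32 (2 and 23 adjusted over the list alone; 6.2e-15, and adjusted p = 0.0138 with an estimated correlation). Cyp2e1, which oxidizes ethanol, was 3.08-fold lower. Fatty acid oxidation had 0 and 12 of 30 (0 and 18 adjusted over the list alone; 3.57e-07, and adjusted p = 0.0138 with an estimated correlation). Acsl1 was 5.24-fold lower. Gluconeogenesis had 1 and 8 of 15 (1 and 12 adjusted over the list alone; 0.000186, and adjusted p = 0.0426 with an estimated correlation). Plasma proteins had 2 and 26 of 53 (4 and 33 adjusted over the list alone; 4.53e-10, but adjusted p = 0.0763 with an estimated correlation). Apom was 6.5-fold and Apoc3 5.01-fold lower. Urea cycle and amino acid catabolism had 0 and 11 of 30 (0 and 14 adjusted over the list alone; 6.56e-06, but adjusted p = 0.0591 with an estimated correlation). The tryptophan-degrading Kynu was 6.79-fold lower. Methionine and one-carbon metabolism had 1 and 7 of 17 (3 and 8 adjusted over the list alone; 0.00538, but adjusted p = 0.135 with an estimated correlation). Pemt, which makes phosphatidylcholine, was 5.18-fold lower. Lipogenesis and sterol synthesis had 1 and 15 of 30 (2 and 18 adjusted over the list alone; 6.61e-06, but adjusted p = 0.0527 with an estimated correlation). Ribosomal proteins had 25 and 0 of 45 (26 and 0 adjusted over the list alone; 1.97e-17, but adjusted p = 0.0754 with an estimated correlation). Bile duct and oval cell markers had 4 and 0 of 8 (5 and 0 adjusted over the list alone; 2e-05, but adjusted p = 0.0527 with an estimated correlation). Krt19 was 8.25-fold higher. Glycolysis had 3 and 1 of 17 (3 and 1 adjusted over the list alone; 0.00118, but adjusted p = 0.0606 with an estimated correlation). The muscle-type aldolase Aldoa was 5.38-fold higher. On array 3, which shares its Cy5 image with nodule array 3, the list median was 0.06 for ribosomal proteins (others 0.78 to 1.22) and 0.4 for NRF2 genes (others 1.36 to 1.7), and the array weight was 0.24. Myc (2.97-fold, adjusted p = 0.0005) and the mitotic kinase Cdk1 (2.15-fold, 0.00767, above background on 3 of 4 HCC arrays and 1 of 4 normal-liver channels) rose, and the Cdk1 call ended without array 1 (log2 0.95). Afp (-0.52 ± 0.4, 0.485, another probe of opposite sign), Cps1 (adjusted p = 0.594) and Top2a (adjusted p = 0.972) did not pass.

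In total 1112 probes differed between F344 HCC and normal liver, 374 higher and 738 lower. The count was 966 with the replicate numbers as a block (598 on the F344 lesion arrays alone) and 1016 with print as a block. It was 253 on the 3 older-print arrays, 50 on the 1 newer-print array, 732 without array 3 and 710 without array 5. With median centring it was 1135 (164 higher, 971 lower). Scale normalization ended the Pla2g7 call (log2 3.35), and the dye term gave 379 probes and ended the Myc call (1.43) and that of the lipogenesis list (adjusted p = 0.147, in a range of 4.21e-08 to 0.147).

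In BN HCC, Gstp1 rose 69.4-fold (log2 change 6.12 ± 0.44 SE, n = 4 arrays, adjusted p = 9e-10). Anxa1, a phospholipid-binding protein, rose 16.9-fold (4.08 ± 0.57, adjusted p = 1.23e-05) and mesothelin, Msln, 16.8-fold (4.07 ± 0.56, adjusted p = 1.12e-05, detected in normal liver on 1 of 4 arrays). The tetraspanin Tspan8 rose 15.4-fold (3.94 ± 0.46, adjusted p = 1.75e-06, likewise on 1 of 4). G6pc1, the glucose-6-phosphatase that releases glucose from liver, fell 11.9-fold (-3.57 ± 0.49, adjusted p = 1.2e-05). All 4 arrays showed these directions. Further rises were those of Car2 (13.6-fold), Aldh3a1 (11.3-fold), the neurofilament gene Nefl (at least 10.27-fold) and the dynein assembly factor Dnaaf1 (at least 8.06-fold), the last 2 above background on 0 of 4 normal-liver channels. Further falls were those of Stac3 (at least 9-fold, above background on 0 of 4 HCC arrays), Kynu (6.69-fold), Cyp2c7 (6.21-fold), Cyp2c11 (6.08-fold), the peroxisomal oxidase Hao2 (6.04-fold), Cyp4a8 (5.99-fold) and the insulin-like growth factor carrier Igfbp1 (5.96-fold, detected on 1 of 4 HCC arrays).

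Among gene groups in BN HCC, 14 of 18 preneoplastic and tumour markers rose and 1 fell (16 and 1 adjusted over the list alone; list adjusted p = 5.31e-19, and adjusted p = 0.00198 with an estimated correlation). NRF2 and glutathione genes had 18 and 0 of 25 (19 and 0 adjusted over the list alone; 7.54e-18, and adjusted p = 0.0218 with an estimated correlation). Array 5 stood apart, with a list median of 0.77 against 1.77 to 1.83 on the others. The glutathione peroxidase Gpx2 was 7.5-fold and Gclm 6.57-fold higher. Cytochromes P450 had 0 and 24 of 32 (0 and 27 adjusted over the list alone; 1.12e-12, and adjusted p = 0.0218 with an estimated correlation). Urea cycle and amino acid catabolism had 0 and 17 of 30 (0 and 23 adjusted over the list alone; 2.3e-10, and adjusted p = 0.014 with an estimated correlation). Agxt was 4.39-fold lower. Fatty acid oxidation had 0 and 16 of 30 (0 and 20 adjusted over the list alone; 8.7e-09, and adjusted p = 0.0105 with an estimated correlation). Ribosomal proteins had 34 and 0 of 45 (37 and 1 adjusted over the list alone; 2.5e-29, and adjusted p = 0.0255 with an estimated correlation). Bile duct and oval cell markers had 4 and 0 of 8 (4 and 0 adjusted over the list alone; 3.59e-07, and adjusted p = 0.027 with an estimated correlation). The keratin Krt19 was 10.5-fold and Epcam 8.54-fold higher. Fibroblast and matrix markers had 8 and 1 of 16 (8 and 1 adjusted over the list alone; 4.35e-06, but adjusted p = 0.095 with an estimated correlation). Tagln of smooth muscle was 5.71-fold, collagen VI Col6a3 5.35-fold and biglycan Bgn 5.33-fold higher. Plasma proteins had 1 and 26 of 53 (1 and 33 adjusted over the list alone; 4.85e-10, but adjusted p = 0.0763 with an estimated correlation). Methionine and one-carbon metabolism had 0 and 7 of 17 (0 and 8 adjusted over the list alone; 0.00196, but adjusted p = 0.101 with an estimated correlation), and gluconeogenesis 1 and 6 of 15 (1 and 11 adjusted over the list alone; 0.00135, but adjusted p = 0.0721 with an estimated correlation). The methyl transferase Gnmt was 3.97-fold and Pck1 4.76-fold lower. Glycolysis had 6 and 2 of 17 (6 and 2 adjusted over the list alone; 0.0195, but adjusted p = 0.156 with an estimated correlation). MHC and interferon genes had 3 and 0 of 21 (3 and 0 adjusted over the list alone; 0.0141, but adjusted p = 0.219 with an estimated correlation). The class II gene RT1-Da was 6.01-fold and its invariant chain Cd74 3.3-fold higher. Macrophage markers had 4 and 2 of 17 (6 and 2 adjusted over the list alone; 0.0168, but adjusted p = 0.253 with an estimated correlation). Lysozyme Lyz2 was 5.55-fold higher. RNA quality and immediate early genes had 3 and 1 of 15 (4 and 1 adjusted over the list alone; 0.0257, but adjusted p = 0.279 with an estimated correlation). Myc (0.83 ± 0.29, 0.0522), Cyp2e1 (-0.77 ± 0.32, 0.108), Cps1 (adjusted p = 0.103), Cdk1 (0.44 ± 0.27, 0.307), Top2a (adjusted p = 0.962) and Afp (-0.24 ± 0.4, 0.762, another probe of opposite sign) did not pass.

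In BN HCC 1808 probes differed from normal liver, 629 higher and 1179 lower. The count was 1616 with the replicate numbers as a block, and 1691 with print as a block. It was 3 on the 1 older-print array, 2311 on the 3 newer-print arrays, 1015 without array 3 and 1047 without array 7. With median centring, which moved the median of all probes by -0.12 here and by -0.2 in BN nodules, it was 1916 (259 higher, 1657 lower) and the calls of the MHC list (adjusted p = 0.084, in a range of 9.65e-07 to 0.261), the macrophage list (0.186, in a range of 0.000169 to 0.266) and the RNA quality list (0.185, in a range of 0.00905 to 0.279) ended. The RNA quality call also ended without a filter (0.0698) and with print as a block (0.0516). It was 644 with the dye term (339 and 305).

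The HCC changes of both strains were compared to see which are common. Of the 374 probes higher in F344 HCC and the 629 higher in BN HCC, 223 were shared, where independent lists would share 19.3. Of the 738 and 1179 lower probes, 428 were shared, where independent lists would share 71.5. Of the probes called in F344 HCC, 93.9% of those higher and 95.5% of those lower had the same sign in BN HCC, and 1 and 3 were called in the opposite direction there. In the nodules, all 5 probes higher in BN were among the 409 higher in F344, and 4 of the 16 lower in BN among the 499 lower in F344. Genes are not independent, so no p-value was computed for the overlap.

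**Figure D2:**
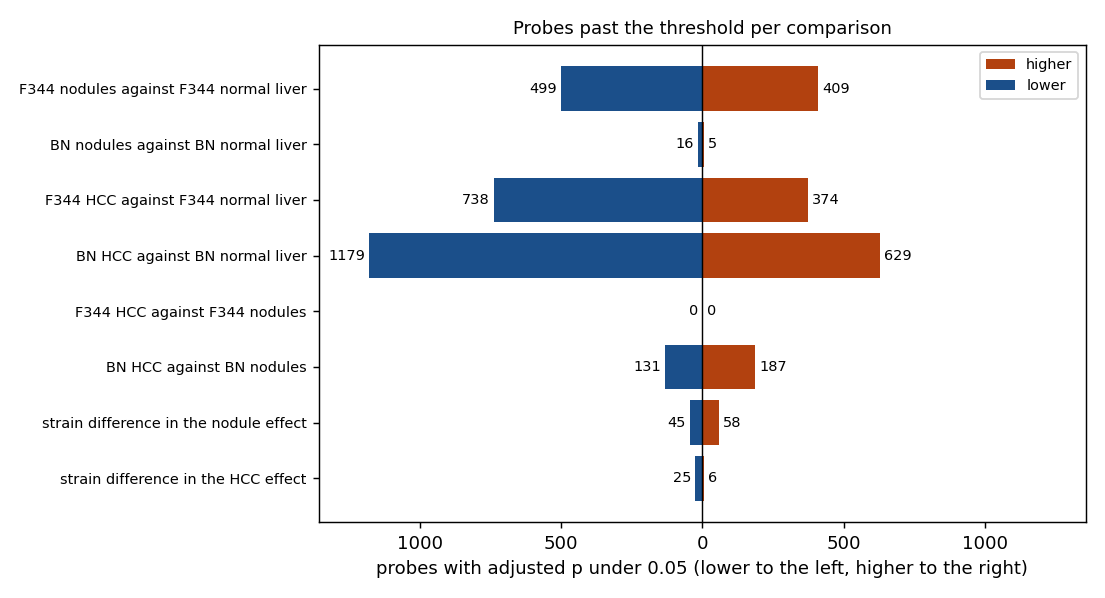
Bars give the number of probes with adjusted p under 0.05 (horizontal axis) that were lower (blue, to the left) or higher (orange, to the right) in each comparison. BN nodules had 5 higher and 16 lower probes and BN HCC 629 and 1179, and 0 probes passed between F344 HCC and F344 nodules.

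The lesions of one strain were compared to find what differs between the early lesion and the carcinoma. Between F344 HCC and F344 nodules, 0 probes passed in limma, with 801 at an unadjusted p under 0.05. The differences in Gstp1 (log2 0.26 ± 0.63 SE, n = 4 and 4 arrays on 7 slides, adjusted p = 0.963), Akr7a3 (-1.41 ± 0.42, 0.72), Nqo1 (-0.36 ± 0.49, 0.925), Cyp2c11 (-0.58 ± 0.59, 0.887), Cyp2e1 (-0.36 ± 0.45, 0.913), Myc (-0.59 ± 0.41, 0.838), Cdk1 (0.61 ± 0.38, 0.827), Cps1 (adjusted p = 0.979), Top2a (adjusted p = 0.985) and Afp (0.12 ± 0.56, 0.983) did not pass. As lists, macrophage markers were higher in HCC (median 0.41, adjusted p = 0.00229, but adjusted p = 0.144 with an estimated correlation). Oxidative phosphorylation (-0.22, 0.00554, but adjusted p = 0.368 with an estimated correlation), methionine and one-carbon metabolism (-0.42, 0.00915, but adjusted p = 0.161 with an estimated correlation) and lipogenesis (-0.46, 0.011, but adjusted p = 0.24 with an estimated correlation) were lower in HCC. Fatty acid oxidation (-0.28, 0.0124, but adjusted p = 0.156 with an estimated correlation) and NRF2 genes (-0.32, 0.0158, but adjusted p = 0.529 with an estimated correlation) were lower as well, and of the 6 lists only NRF2 had a member past the threshold adjusted over the list alone (0 higher, 1 lower). The macrophage call ended with median centring (0.151, in a range over all alternatives of 0.000301 to 0.419, the highest from the newer print), and the other 5 ended without some array. Without nodule array 1 lipogenesis (0.0642) and fatty acid oxidation (0.0504) ended, without nodule array 3 NRF2 (0.0655), methionine (0.0969) and oxidative phosphorylation (0.0736), and without nodule array 7 NRF2 (0.0926). Without HCC array 1 NRF2 (0.0681) and lipogenesis (0.127) ended, without HCC array 3 NRF2 (0.232), and without HCC array 5 methionine (0.113), fatty acid oxidation (0.113) and oxidative phosphorylation (0.154). With 1 array left out the p ranged from 0.00183 to 0.232 for NRF2, from 0.00285 to 0.113 for methionine, from 0.00181 to 0.127 for lipogenesis, from 0.000387 to 0.113 for fatty acid oxidation and from 0.00111 to 0.154 for oxidative phosphorylation.

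The count between F344 HCC and nodules was 0 with the replicate numbers as a block (722 at an unadjusted p under 0.05, and 510 on the F344 lesion arrays alone) and 0 with print as a block (813). It was 0 on the older print (430). The newer-print arrays of both groups are scans of one slide, so that print offers no test. The count was 0 without both pairs of arrays that share a slide or image (998), 1 without nodule array 1, nodule array 7 or HCC array 7, 1 in the deposited values and 3 with flag code 3 only. It was 942 in the design with all 38 files as separate arrays, a dye intercept and a strain column. The dye intercept cancels in this difference and the strain column is 0 on lesion arrays, so neither enters its estimate. The scaled copies stood there as separate replicates, which they are not, so the 942 does not count as evidence of a difference.

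Between BN HCC and BN nodules, the membrane protein genes Msln and Tspan8 were 15.7-fold (log2 3.97 ± 0.79 SE, n = 4 and 4 arrays, adjusted p = 0.0056) and 13.7-fold (3.78 ± 0.66, adjusted p = 0.00207) higher in HCC, and in nodules above background on 1 and 3 of 4 arrays. The matrix genes Mgp and Col1a2 were 11.1-fold (3.48 ± 0.65, adjusted p = 0.00333) and 8.78-fold (3.13 ± 0.61, adjusted p = 0.00476) higher, in nodules above background on 3 and 1 of 4. G6pc1 was 12.6-fold lower (-3.66 ± 0.7, adjusted p = 0.00389) and Stac3 lower (adjusted p = 0.001), above background on 0 of 4 HCC arrays, so no fold is given. Of the cytochromes P450, 0 rose and 9 of 32 fell (0 and 22 adjusted over the list alone; list adjusted p = 3.99e-17, and adjusted p = 0.0111 with an estimated correlation). Cyp3a18 was 6.08-fold lower, and Cyp3a9 was lower (adjusted p = 0.00159) and above background on 0 of 4 HCC arrays. Urea cycle and amino acid catabolism had 0 and 7 of 30 (0 and 17 adjusted over the list alone; 2.82e-13, and adjusted p = 0.0105 with an estimated correlation). Fatty acid oxidation had 0 and 4 of 30 (0 and 12 adjusted over the list alone; 5.46e-11, and adjusted p = 0.00549 with an estimated correlation). Gluconeogenesis had 0 and 2 of 15 (0 and 3 adjusted over the list alone; 0.000144, and adjusted p = 0.0411 with an estimated correlation). Preneoplastic and tumour markers had 7 and 0 of 18 (12 and 1 adjusted over the list alone; 1.14e-11, and adjusted p = 0.00688 with an estimated correlation). The iron-binding lipocalin Lcn2 was higher (adjusted p = 0.000498) and above background on 0 of 4 nodule arrays. Ribosomal proteins had 19 and 0 of 45 (32 and 0 adjusted over the list alone; 7.81e-26, and adjusted p = 0.0329 with an estimated correlation). Bile duct and oval cell markers had 4 and 0 of 8 (4 and 0 adjusted over the list alone; 6.86e-07, and adjusted p = 0.0294 with an estimated correlation). Osteopontin, Spp1, was higher (adjusted p = 0.00175, in nodules above background on 1 of 4 arrays and 0 of 4 normal-liver channels, so no fold is given) and Krt19 6.14-fold higher. Fibroblast and matrix markers had 8 and 0 of 16 (8 and 0 adjusted over the list alone; 3.35e-08, but adjusted p = 0.0527 with an estimated correlation). Tagln was 6.11-fold higher (on 1 of 4 nodule arrays). NRF2 genes had 3 and 0 of 25 (11 and 0 adjusted over the list alone; 1.94e-09, but adjusted p = 0.084 with an estimated correlation). Gpx2 was 5.55-fold higher. Plasma proteins had 0 and 3 of 53 (1 and 10 adjusted over the list alone; 1.53e-10, but adjusted p = 0.0721 with an estimated correlation). Methionine and one-carbon metabolism had 0 and 3 of 17 (0 and 6 adjusted over the list alone; 9.25e-05, but adjusted p = 0.0516 with an estimated correlation). Lipogenesis had 0 and 0 of 30 (0 and 2 adjusted over the list alone; 0.00804, but adjusted p = 0.219 with an estimated correlation). Glycolysis had 2 and 1 of 17 (2 and 1 adjusted over the list alone; 0.0322, but adjusted p = 0.194 with an estimated correlation). Its call ended without nodule array 7 (0.148) or HCC array 3 (0.0759), in a leave-one-out range of 0.00852 to 0.148. MHC and interferon genes had 2 and 0 of 21 (2 and 0 adjusted over the list alone; 0.0414, but adjusted p = 0.308 with an estimated correlation). That call ended without nodule array 5 (0.0706) or HCC arrays 1 (0.0686), 3 (0.0595) or 7 (0.0537), in a range of 0.0265 to 0.0706.

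In total 318 probes differed between BN HCC and BN nodules, 187 higher and 131 lower in HCC. Among the sentinels Gstp1 was higher in HCC (log2 2.26 ± 0.63, adjusted p = 0.0479), a call that ended when any array but nodule array 5 was left out (log2 1.85 to 2.71), and Cyp2c11 lower (-2.71 ± 0.59, 0.00942), a call that ended without HCC array 3 (-2.41). The differences in Nqo1 (1.58 ± 0.49, 0.0858), Myc (0.96 ± 0.41, 0.282), Cyp2e1 (-1.03 ± 0.45, 0.294), Cps1 (adjusted p = 0.378), Cdk1 (0.75 ± 0.38, 0.402), Akr7a3 (0.44 ± 0.42, 0.758), Afp (-0.53 ± 0.56, 0.796) and Top2a (adjusted p = 0.972) did not pass. The count was 248 with the replicate numbers as a block, and 332 with print as a block. It was 0 on the 2 older-print arrays (141 at an unadjusted p under 0.05), 456 on the newer print, 184 and 151 without nodule arrays 3 and 7, and 198, 131 and 157 without HCC arrays 1, 3 and 7. It was 58 with median centring and 132 with scale normalization (94 higher, 38 lower), which ended the calls of G6pc1 (log2 -3.29) and Stac3.

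**Figure D3:**
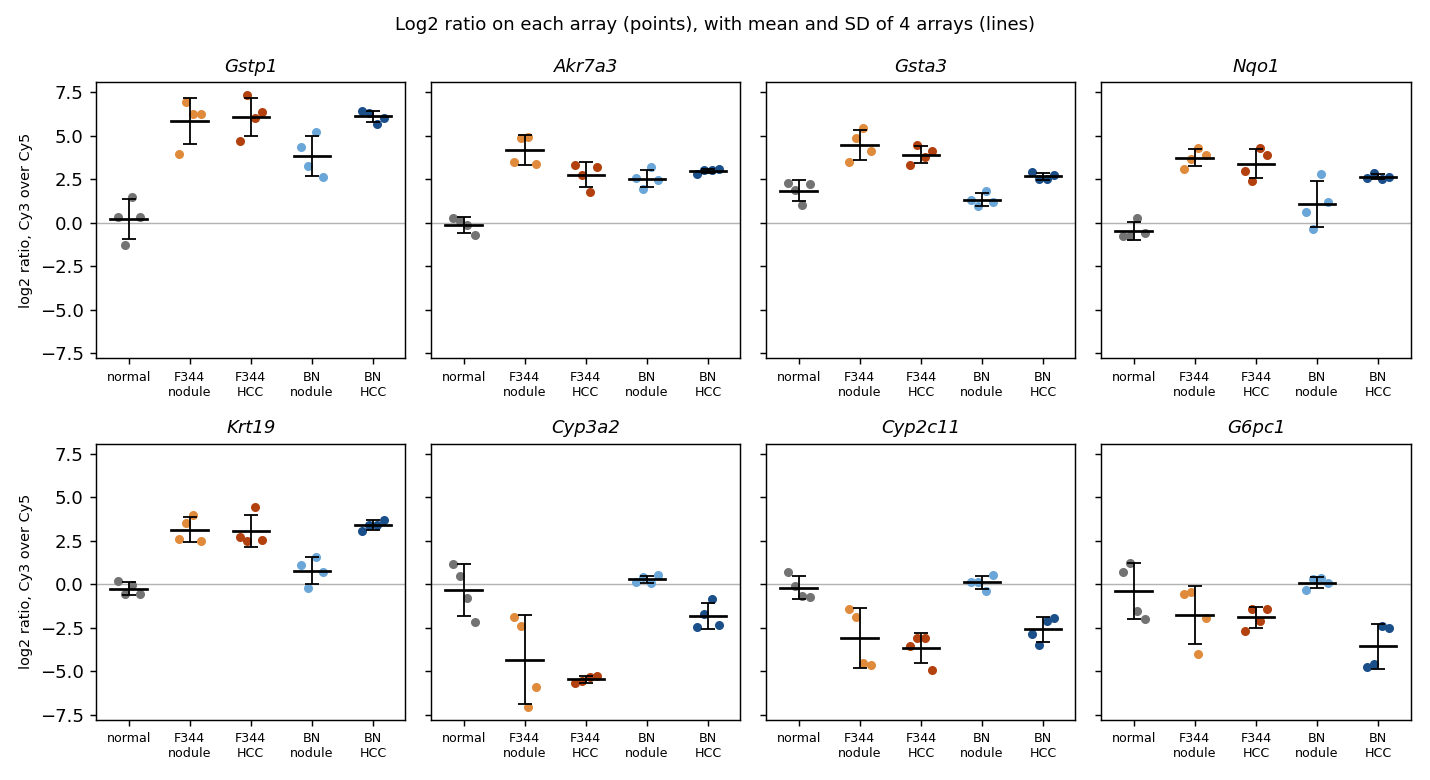
Log2 ratio of Cy3 over Cy5 (vertical axis) of 8 genes on each of the 4 arrays per group (points), with the mean (long line) and SD (error bar). For normal liver the points are 4 slides of F344 against BN liver without a settled direction, and the mean of Gstp1 was 3.86 in BN nodules and 6.12 in BN HCC.

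The normal-liver slides set the strains against each other, and their files name opposite dye orientations for one slide, so each value is given as a ratio between the strains without a direction. The bile acid and steroid hydroxylase Cyp7b1 differed 8.44-fold (log2 ratio 3.08 ± 0.29 SE, n = 4 slides, adjusted p = 3.21e-07). Ubd, a ubiquitin-like protein induced by interferon, differed on the other side of 0 (adjusted p = 2.26e-06) and so did the matrix protein Dpt, 7.58-fold (-2.92 ± 0.31, adjusted p = 1.49e-06), and all 4 slides went the same way for each. Cyp17a1 of steroid synthesis (5.77-fold), Gsta3 (3.59-fold) and the phospholipid-binding Anxa5 (2.8-fold) were on the side of Cyp7b1. Rapgef2 (11.4-fold, another probe of opposite sign), Ctdsp1 (5.41-fold), and Oas1a (adjusted p = 0.00235) and Ifi27 (2.63-fold), which interferon induces, were on the side of Ubd. So was Cdh17 (adjusted p = 0.00238), a call that ended without slide 2 (0.0954, in a leave-one-out range of 0.000769 to 0.0954). In Ubd, Oas1a and Cdh17 one channel was above background on 0 of 4 slides, so no fold is given. MHC and interferon genes had 3 of 21 called on the side of Ubd (6 adjusted over the list alone; list adjusted p = 8.93e-09, and adjusted p = 0.0138 with an estimated correlation). Lipogenesis and sterol synthesis had 0 of 30 called (6 on the side of Ubd adjusted over the list alone; 4.85e-10, and adjusted p = 0.0138 with an estimated correlation). Macrophage markers had 0 of 17 (0 adjusted over the list alone; 0.000403, but adjusted p = 0.095 with an estimated correlation). On the other side were the urea cycle genes, 1 of 30 (1 adjusted over the list alone; 1.99e-08, and adjusted p = 0.0255 with an estimated correlation), and cytochromes P450, 4 of 32 (7 adjusted over the list alone, against 1 on the side of Ubd; 3.7e-07, but adjusted p = 0.0763 with an estimated correlation). Gstp1 (0.22 ± 0.44), Akr7a3 (-0.12 ± 0.29), Nqo1 (-0.45 ± 0.35), Cyp2c11 (-0.2 ± 0.42), Myc (0.14 ± 0.29), Cdk1, Cps1, Top2a and Afp (-0.08 ± 0.4) did not pass, each with an adjusted p of 1.0. Cyp2e1 passed (1.42 ± 0.32, 0.0426), a call that ended with any 1 slide left out (1.29 to 1.57).

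In total 38 probes differed in normal liver, 16 on one side and 22 on the other, and dye and strain cannot be told apart in them. The count was 718 with scale normalization (234 and 484), 363 with array weights (145 and 218) and 29 with print as a block. It was 0 on the 1 older-print slide (144 at an unadjusted p under 0.05), 25 on the 3 newer-print slides, 17 without slide 2 and 22 without any other slide. With median centring, which moved the median of all probes by -0.18, it was 80 (4 and 76) and the Gsta3 call ended (1.07). With the normal-liver arrays of one number as a random block it was 0 (88 at an unadjusted p under 0.05). The scans of each slide entered that fit as opposite orientations, so the ratio of a slide cancels. A count near 0 was therefore fixed in advance.

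The strain difference in a lesion effect, F344 minus BN, tests whether the strains differ in how far the lesion departs from normal liver. The F344 lesion arrays were mostly of the older print and the BN lesion arrays mostly of the newer, so print differs along with strain here. In nodules, Gsta3 was 8.97-fold higher (log2 difference 3.17 ± 0.4 SE, n = 4 and 4 arrays, adjusted p = 0.000109) and Pla2g7 12.5-fold (3.65 ± 0.59, adjusted p = 0.00175) in F344 relative to BN. So were Ptgr1 7.88-fold (2.98 ± 0.47, adjusted p = 0.00128), Nqo1 6.43-fold (2.68 ± 0.49, adjusted p = 0.00406) and the matrix protein Smoc2 (adjusted p = 0.00175, no fold, above background on 0 of 4 BN nodule arrays). Cyp3a2 was 24.4-fold lower (-4.61 ± 0.77, adjusted p = 0.00232), Cyp3a23-3a1 16.0-fold (-4.0 ± 0.68, adjusted p = 0.00267), Cdh17 12.7-fold (-3.67 ± 0.66, adjusted p = 0.00406) and Cyp2c11 9.26-fold (-3.21 ± 0.59, adjusted p = 0.00406). Sult1e1 was 15.9-fold lower (-3.99 ± 0.86, adjusted p = 0.0181), a call that ended without F344 nodule array 5 (log2 -3.29) or 7 (-3.03) or BN nodule array 3 (-3.99) or 7 (-3.94). Myc was 4.85-fold (adjusted p = 0.00406) and Krt19 5.15-fold (0.00534) higher. In the lists, cytochromes P450 had 0 members higher and 10 lower of 32 (1 and 17 adjusted over the list alone; list adjusted p = 1.2e-16, and adjusted p = 0.0116 with an estimated correlation). NRF2 and glutathione genes had 7 and 0 of 25 (16 and 0 adjusted over the list alone; 1.11e-13, and adjusted p = 0.0411 with an estimated correlation). Preneoplastic and tumour markers had 3 and 0 of 18 (10 and 0 adjusted over the list alone; 3.6e-06, and adjusted p = 0.0294 with an estimated correlation). Plasma proteins had 1 and 1 of 53 (1 and 19 adjusted over the list alone; 1.15e-11, but adjusted p = 0.0591 with an estimated correlation). The differences in Gstp1 (1.99 ± 0.63, 0.139), Akr7a3 (1.62 ± 0.42, 0.0592), Cyp2e1 (-1.52 ± 0.45, 0.114), Cdk1 (0.79 ± 0.38, 0.367), Cps1 (adjusted p = 0.603), Top2a (adjusted p = 0.947) and Afp (-0.93 ± 0.56, 0.495) did not pass.

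In total 103 probes differed between the strains in the nodule effect, 58 higher and 45 lower in F344. The count was 0 with scale normalization (1008 at an unadjusted p under 0.05), which ended every gene call named here, 58 with median centring (40 and 18; median of all probes moved by 0.12), and 70 with the replicate numbers as a block. It was 74 with print as a block, 1 on the older and 12 on the newer print (1 array in 1 of the groups of each), 175 and 52 without F344 nodule arrays 1 and 5, and 51 and 55 without BN nodule arrays 3 and 7.

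In HCC, Igfbp1 was 16.7-fold higher in F344 relative to BN (log2 difference 4.07 ± 0.63 SE, n = 4 and 4 arrays, adjusted p = 0.00113). The cadherin-like Fat1 was 6.56-fold lower (-2.71 ± 0.42, adjusted p = 0.00113), the scavenger receptor Dmbt1 6.88-fold lower (-2.78 ± 0.46, adjusted p = 0.00276, above background on 1 of 4 HCC arrays of each strain) and the phosphatase Dusp1 5.07-fold lower (-2.34 ± 0.36, adjusted p = 0.00113). MHC and interferon genes had 0 members called of 21 (0 higher and 6 lower adjusted over the list alone) and were lower as a list (3.25e-06, and adjusted p = 0.0329 with an estimated correlation). Fibroblast and matrix markers had 0 higher and 1 lower of 16 (0 and 5 adjusted over the list alone; 2.31e-05, but adjusted p = 0.122 with an estimated correlation). Gstp1 (-0.01 ± 0.63, 0.997), Akr7a3 (-0.23 ± 0.42, 0.895), Nqo1 (0.74 ± 0.49, 0.634), Cyp2c11 (-1.07 ± 0.59, 0.548), Cyp2e1 (-0.85 ± 0.45, 0.535), Myc (0.73 ± 0.41, 0.56), Cdk1 (0.66 ± 0.38, 0.566), Cps1 (adjusted p = 0.794), Top2a (adjusted p = 0.976) and Afp (-0.28 ± 0.56, 0.907) did not pass.

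In total 31 probes differed between the strains in the HCC effect, 6 higher and 25 lower in F344. The count was 31 with the replicate numbers as a block, 14 with print as a block, 1 on the older and 14 on the newer print (1 array in 1 of the groups of each), and 10, 16 and 17 without BN HCC arrays 3, 5 and 7. It was 11 with median centring (6 and 5), which ended the Dusp1 call. It was 6 with scale normalization (2 and 4), which ended the calls of Igfbp1 (log2 3.4) and Dmbt1 (-2.38). It was 19 without both pairs that share a slide or image, which ended the Fat1 call (-2.43).

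**Figure D4:**
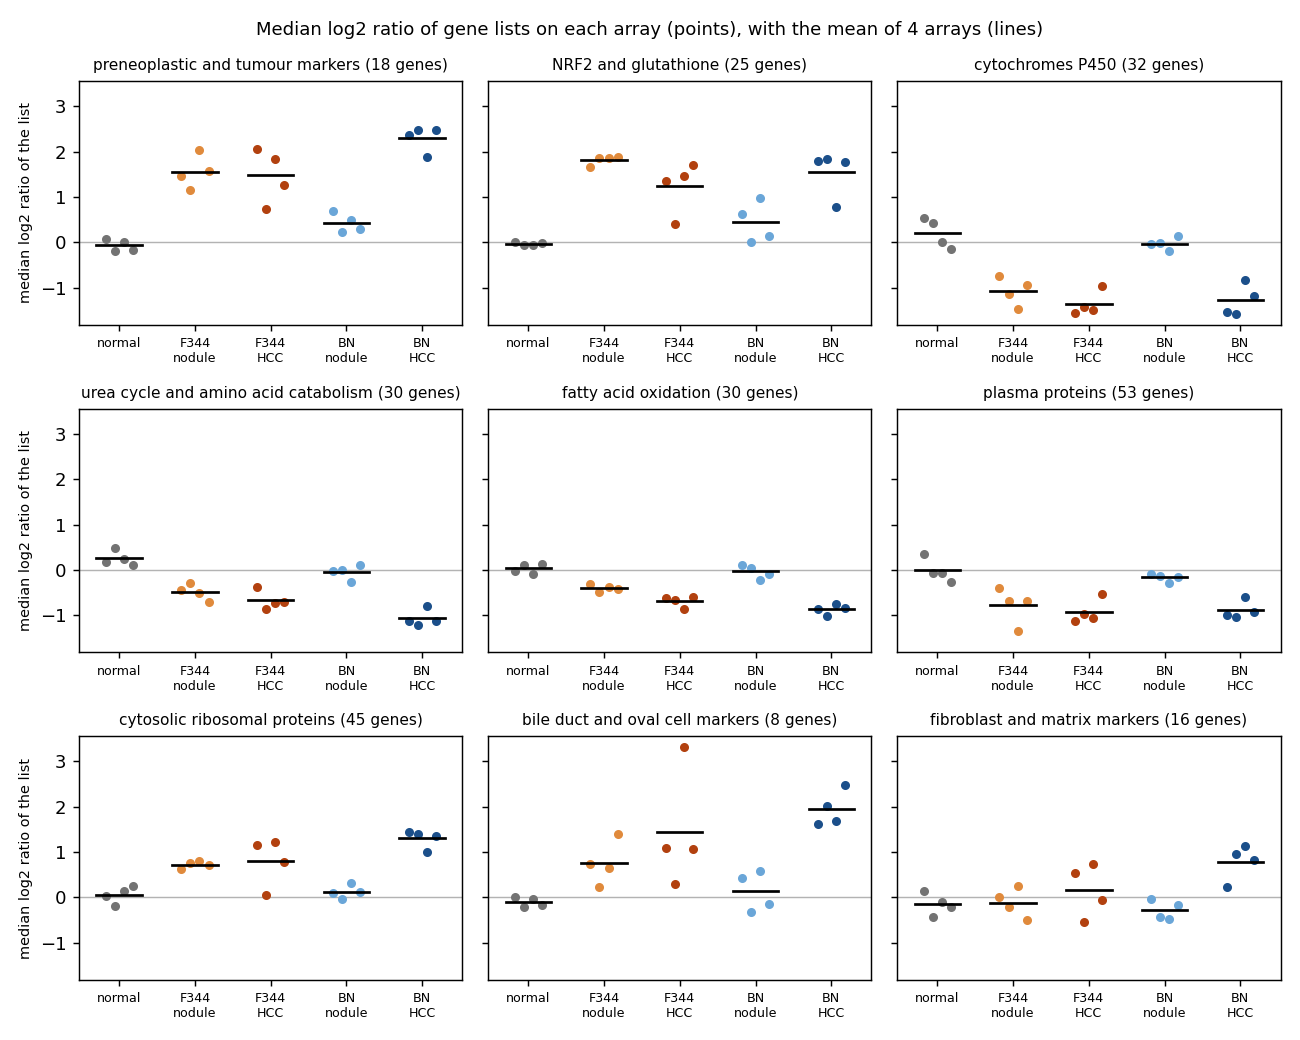
Median log2 ratio over the genes of 9 lists (vertical axis) on each of the 4 arrays per group (points), with the mean of the arrays (line). For normal liver the points are 4 slides without a settled direction, and the cytochromes P450 lay below 0 on every F344 lesion array and every BN HCC array.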

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

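The tests of mixed prints, of spread shared with more variable arrays, of dye bias and of a strain difference between lesion and reference were chosen only after the result was seen.

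Of 158 sets of 4 array values tested for one value far from the other 3 (Dixon's test at 95%), 6 had one, and chance gives about 1 in 20. On F344 nodule array 5, Slc27a5 was at -7.01 (others -2.4 to -1.52) and Cyp4a3 at -4.63 (others -2.43 to -2.25). On F344 nodule array 7, Cdh17 was at -4.17 (others -2.48 to -2.14). On F344 nodule array 1 the NRF2 list median was 1.67 (others 1.85 to 1.88) and the gluconeogenesis list median -0.35 (others -0.47 to -0.46). On BN HCC array 5 the NRF2 list median was 0.77 (others 1.77 to 1.83).

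The nodule effect differed between the strains (F344 minus BN) in 103 probes by the test of the difference itself. The named genes, with fitted log2 differences, were Pla2g7 (3.65), Gsta3 (3.17), Ptgr1 (2.98), Nqo1 (2.68), Cyp3a2 (-4.61), Cyp3a23-3a1 (-4.0), Sult1e1 (-3.99), Cdh17 (-3.67) and Cyp2c11 (-3.21), and without a size Smoc2 (adjusted p = 0.00175), above background on 0 of 4 BN nodule arrays. The lists that differed, with their adjusted p, were preneoplastic and tumour markers (3.6e-06), NRF2 and glutathione (1.11e-13), cytochromes P450 (1.2e-16), urea cycle and amino acid catabolism (0.000128), plasma proteins (1.15e-11), gluconeogenesis (0.0207), lipogenesis (0.000562), fatty acid oxidation (0.000613), ribosomal proteins (2.48e-07) and bile duct markers (0.0142). With an estimated correlation, urea cycle (adjusted p = 0.095), plasma proteins (0.0591), gluconeogenesis (0.176), lipogenesis (0.115), fatty acid oxidation (0.0646), ribosomal proteins (0.284) and bile duct markers (0.238) did not pass, and the first 3 named did. The gluconeogenesis call also ended without F344 nodule array 7 (0.0552), and the bile duct call without F344 nodule array 7 (0.0926) or BN nodule array 7 (0.0612), in leave-one-out ranges of 0.0133 to 0.0552 and 0.00395 to 0.0926.

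The HCC effect differed between the strains in 31 probes by the same kind of test. The named genes were Igfbp1 (4.07), Prodh2 (1.87), Cyp3a23-3a1 (-3.66), Cyp3a2 (-3.63), Dmbt1 (-2.78), Fat1 (-2.71) and Synm (-2.46), and without a size Cyp17a1 (adjusted p = 0.0268), above background on 0 of 4 F344 HCC arrays. With 1 array left out, the call ended in some cases for Cyp17a1 (adjusted p 0.0232 to 0.142), Prodh2 (0.0045 to 0.0751), Cyp3a23-3a1 (0.0102 to 0.0693), Cyp3a2 (0.0496 to 0.138) and Synm (0.0173 to 0.0641). The lists that differed were preneoplastic and tumour markers (0.00342), urea cycle (0.015), lipogenesis (0.00582), ribosomal proteins (1.74e-07), MHC and interferon genes (3.25e-06) and fibroblast markers (2.31e-05). With an estimated correlation, only MHC and interferon genes passed (0.0329), and the others were at 0.129, 0.284, 0.205, 0.284 and 0.122. The urea cycle call ended without F344 HCC array 1 (0.0892) or 7 (0.06) or BN HCC array 1 (0.0574) or 3 (0.0721), and the lipogenesis call without F344 HCC array 1 (0.0593), in leave-one-out ranges of 0.000734 to 0.0892 and 0.00067 to 0.0593.

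Other splits of the arrays were counted for each comparison. Among the 35 splits of 8 arrays into 4 and 4, only the real one (1 of 35) gave as many probes for BN HCC against BN nodules (318, highest other 1), the strain difference in nodules (103, highest other 5) and the strain difference in HCC (31, highest other 2). Chance is unlikely there but not excluded, since 1 of 35 is the lowest share possible. For both strain differences the real split also parts the prints, with 3 older-print arrays on the F344 side and 1 on the BN side. These splits therefore do not tell strain from print. The splits were run with the main processing only. For F344 HCC against F344 nodules the real split gave 0 in limma (801 at an unadjusted p under 0.05). All 35 give at least 0 by construction, so this count says nothing on chance. The highest other, 118, parted arrays 1 and 7 from 3 and 5. The shared slide and image lay within a side, so 118 decides nothing. Of the splits that part as many pairs as the real one, the highest other was 0. For the comparisons with normal liver only 8 sign patterns exist, too few for a share under 0.05. Only the real pattern (1 of 8) gave as many probes, with real value and highest other of 908 and 71 in F344 nodules, 21 and 1 in BN nodules, 1112 and 94 in F344 HCC, 1808 and 0 in BN HCC and 38 and 0 in normal liver.

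The first pattern weighed is the small number of probes that passed in BN nodules (21). With 1 array left out the highest number was 19, which the prediction took as evidence against 1 array out of line. It cannot decide, since these fits kept the spread shared with all other arrays. Of probes above background in both channels on all 8 nodule arrays, 0.287% passed against 20.5% in F344 nodules, which argues against dim signal. BN HCC had the same mixture of prints and 86.1 times the count. The prediction took that as evidence against mixed prints, which was wrong, since a larger change passes despite a spread between prints. With print as a block 17 passed, so taking off an offset common to the arrays of a print did not raise the count. Further explanations are 1 array out of line, mixed prints, a smaller or less uniform change, and a spread shared with more variable arrays. Over the 1808 probes called in BN HCC, the slope on the BN HCC change was 0.21 for BN nodules (0.15 to 0.25 with 1 array left out) and 0.56 for F344 nodules (0.53 to 0.6). On the newer print only, 373 probes passed in BN nodules, and 55 with the BN nodule arrays and the normal-liver slides only. Those slides share in the spread of that fit, with a median SD across probes of 0.31 against 0.55 in BN nodules. Without array 1, the older-print array of the group, 19 passed, so the same 3 BN nodule arrays gave 19 or 373 by the other arrays in the model. Their mean is the same in both fits, so the spread estimated with the other arrays changed the count. Mixed prints, 1 array that widens the spread, and the share of each explanation stay open.

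The second is that 0 probes passed in limma between F344 HCC and F344 nodules (801 at an unadjusted p under 0.05). A slide and an image that stand in both groups could hide a difference, and without both pairs the count was still 0 (998 at an unadjusted p under 0.05). The prediction for that test took a count of 0 as evidence against this explanation, which was wrong, since 2 arrays against 2 recovered only 5.4% of 4-fold changes in simulated data with variances from the fitted prior, and 11.6% with the probes' shrunken variances (7.03% false calls). The slope of the nodule change on the HCC change without the shared pairs was 0.7, which does not decide either. The shared arrays and a like change in both lesions cannot be told apart with the arrays at hand.

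The third is the set of HCC changes common to both strains. Dye bias of the probes would show in the normal-liver slides, where the median ratio signed by the HCC direction was 0.054 (quartiles -0.19 and 0.3) against an HCC change of 1.37 over 651 probes, against dye bias as the cause of the set. With the slide mean taken off as a dye term the counts fell from 1112 to 379 in F344 HCC and from 1808 to 644 in BN HCC (629 to 339 higher, 1179 to 305 lower). Of the 651 probes, 199 were called in both HCC groups and 196 in 1. Their median change was then 1.35, and their median SE rose from 0.28 to 0.4. Whether the calls ended by the larger SE was not tested, and for single probes dye bias stays open. A strain difference between lesion and reference would give a steep slope of the HCC mean on the normal-liver ratio, above or below 0. The larger slope of both strains was 0.17 over the 609 probes with the largest normal-liver ratios. This argues against such a difference for those probes. It does not decide on the common set, since dye and strain are mixed in that ratio and the 609 probes were not chosen from the set. A change in HCC itself may account for the set, as a hypothesis found and tested on the same data.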

How the results depend on the processing

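Of the alternatives, the dye term, flag code 3, the single prints, the F344 replicate block on F344 lesion arrays and the settings without the shared pairs were tests chosen after the data were seen. The 38 separate arrays, with a dye intercept and a strain column, were the design fixed at the start, kept as an alternative once it was replaced. Over all alternatives, the counts stayed within 1.5 times in 116 cases, were lower in 76 and higher in 30. Gene list calls kept direction and side of the threshold in 4271 cases, ended in 203, appeared in 144 and reversed in 15, and for named genes these were 8024, 1537, 44 and 13. The cause of each change below was not tested, apart from fewer probes or arrays where the setting leaves them out. Signal over background limited the probes tested to 12164.

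The comparisons are named here as F nodules, B nodules, F HCC and B HCC (against normal liver, F for F344 and B for BN), F HCC-nodules, B HCC-nodules, normal liver, and the strain differences in nodules and in HCC. Numbers of probes that passed beyond 1.5 times the reported ones were as follows. Median centring: F nodules 482, B nodules 8, B HCC-nodules 58, normal liver 80, strain differences 58 and 11. Scale normalization: F nodules 191, B nodules 13, F HCC 575, B HCC-nodules 132, normal liver 718, strain differences 0 (limma, 1008 at an unadjusted p under 0.05) and 6. Probes above background in both channels on at least 30 files (1439 probes): F nodules 508, B nodules 5, F HCC 676, B HCC 683, strain difference in HCC 67. Array weights: F nodules 363, B HCC 2884, B HCC-nodules 491, normal liver 363, strain difference in nodules 30. Deposited value table: F nodules 468, B nodules 7, F HCC-nodules 1, strain difference in nodules 52. No background correction: B nodules 13, normal liver 74, strain differences 180 and 69. Edwards background correction: B nodules 13, strain difference in HCC 51. No filter: B nodules 13. Arrays of the comparison only: B nodules 55, B HCC 3372, strain difference in nodules 13. For a lesion against normal liver these arrays include the normal-liver slides. Replicate block: B nodules 11. F344 replicate block on F344 lesion arrays: F nodules 438, F HCC 598. Print as a block: strain difference in HCC 14. Older print only: F nodules 99, B nodules 1, F HCC 253, B HCC 3, B HCC-nodules 0 (limma, 141 unadjusted), normal liver 0 (144 unadjusted), strain differences 1 and 1. Newer print only: F nodules 72, B nodules 373, F HCC 50, normal liver 25, strain differences 12 and 14. All 38 files as separate arrays: F nodules 1958, B nodules 362, F HCC 1828, F HCC-nodules 942, B HCC-nodules 1917, normal liver 0 (44 unadjusted), strain differences 2215 and 1209. Dye term: F nodules 244, F HCC 379, B HCC 644. Flag code 3 only (740 probes): F nodules 365, B nodules 8, F HCC 445, B HCC 439, F HCC-nodules 3, strain difference in HCC 47. Without the one-slide pair: F HCC-nodules 1. Without the Cy5-image pair: strain difference in nodules 174. Without both pairs: F nodules 567, F HCC 676, strain differences 159 and 19. Normal-liver arrays of one number as a random block: normal liver 0 (88 unadjusted). In that fit and in the one with all 38 files, scans of one slide entered as opposite orientations. The normal-liver count of 0 in both therefore tests nothing. Where an older or newer print leaves 1 array in a group, that array is assumed to vary like the others.

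With 1 array left out the counts ranged from 488 to 1142 in F nodules, 4 to 19 in B nodules, 710 to 1037 in F HCC, 1015 to 1391 in B HCC, 0 to 1 in F HCC-nodules, 131 to 308 in B HCC-nodules, 17 to 22 in normal liver, 51 to 175 in the strain difference in nodules and 10 to 44 in that in HCC.

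Values that changed sign, with their range over all alternatives, were these. With the 38 separate arrays and with the dye term: Oas1a 0.45 and 0.45 in F nodules (-1.39 to 0.45), Gsta3 -0.51 and -0.51 in B nodules (-0.51 to 1.46), Ifi27 0.62 and 0.68 in F HCC (-1.44 to 0.68). With the 38 separate arrays: Cyp2e1 -1.16 in B nodules (-1.16 to 0.39). On the newer print only: Bgn -0.06 in F nodules (-0.06 to 1.49), and in F HCC Foxa2 0.07 (-1.77 to 0.07), Cox5a 0.03 (-1.82 to 0.03), Uqcrq 0.2 (-1.57 to 0.2) and Cox5b 0.33 (-1.58 to 0.33). With median centring: H2az1 -0.03 in B HCC (-0.03 to 0.77). Lists that changed direction, by adjusted p, were lipogenesis in F nodules at 0.866 and 0.808 (0.000342 to 0.866), cytochromes P450 in B nodules at 0.0163 and 0.0121 (0.0121 to 0.92) and urea cycle in B nodules at 0.00133 and 0.00122 (0.00122 to 0.969), each with the 38 separate arrays and with the dye term. On the newer print only these were methionine (0.907; 0.000309 to 0.907) and macrophage markers (0.419; 0.000301 to 0.419) in F HCC-nodules, a setting that compares scans of one slide there, and NRF2 in the strain difference in HCC (0.0357; 0.00493 to 0.915). With median centring they were ribosomal proteins in B nodules (0.33; 7.3e-06 to 0.578) and F HCC-nodules (0.0383; 2.25e-09 to 0.863), and plasma proteins in F HCC-nodules (0.00142; 0.00127 to 0.993; also 0.0223 without F344 nodule array 5) and in the strain difference in HCC (0.000106; 0.000106 to 0.996). With both channels above background on at least 30 files it was endothelial markers in B nodules (0.967; 0.0139 to 0.967).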

Other observations

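The correlations by array number were tests chosen after the data were seen, and no further hypothesis was tested.

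Lists that did not pass in at least 1 of these comparisons gave these adjusted p in F344 nodules, BN nodules, F344 HCC and BN HCC against normal liver. Cell cycle genes were at 0.567, 0.41, 0.0781 and 0.644, growth signalling and transcription factors at 0.989, 0.653, 0.534 and 0.659, and heat shock and ER chaperones at 0.463, 0.134, 0.693 and 0.996. Oxidative phosphorylation was at 0.462, 0.659, 0.182 and 0.189. Lymphocyte markers were at 0.674, 0.656, 0.919 and 0.592, endothelial markers at 0.674, 0.0361, 0.959 and 0.315, and red blood cell markers at 0.872, 0.898, 0.619 and 0.864. MHC and interferon genes were at 0.315, 0.383, 0.212 and 0.0141. RNA quality and immediate early genes were at 0.0646, 0.351, 0.0861 and 0.0257, fibroblast and matrix markers at 0.983, 0.293, 0.18 and 4.35e-06, and macrophage markers at 0.245, 0.267, 0.324 and 0.0168. Lipogenesis was at 0.343 in BN nodules and 0.082 in BN HCC. In BN nodules methionine and one-carbon metabolism was at 0.557, plasma proteins at 0.692, gluconeogenesis at 0.674, glycolysis at 0.573, fatty acid oxidation at 0.698 and bile duct markers at 0.161. Of the lists that did not pass elsewhere, the adjusted p ran from 0.0575 to 0.989 in F344 HCC against nodules, from 0.082 to 0.898 in BN HCC against nodules, from 0.149 to 0.943 in normal liver, and from 0.0515 to 0.851 and 0.0646 to 0.972 in the strain differences in nodules and HCC. The test, median and mean differed in sign for cell cycle genes in BN HCC (test up, median -0.18, mean -0.04), for growth signalling in F344 nodules (test down, median 0.04, mean -0.02), BN nodules (up, -0.07, -0.08), F344 HCC (up, -0.09, 0.02) and BN HCC (up, 0.07, -0.07). They also differed for heat shock in F344 HCC (up, -0.03, -0.04) and BN HCC (up, -0.09, -0.13), RNA quality in BN nodules (up, -0.06, -0.05), lymphocyte markers in F344 HCC (down, 0.06, -0.14) and red blood cell markers in BN nodules (up, 0.03, -0.08). In BN nodules they differed as well for cytochromes P450 (up, 0.02, -0.02), methionine (up, -0.02, -0.01), gluconeogenesis (up, -0.07, -0.05), glycolysis (up, -0.13, -0.02), lipogenesis (up, 0.03, -0.01), fatty acid oxidation (up, -0.04, -0.07), bile duct markers (up, -0.05, 0.18) and macrophage markers (up, -0.08, 0.06).

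The group mean of each probe was taken off its log2 ratios, which left the deviation of each array from its group. For nodule and HCC arrays of one number these deviations were correlated across probes, which are not independent replicates. The correlations were 0.146, 0.205, 0.111 and 0.385 in F344 (numbers 1, 3, 5 and 7, of which 3 share an image and 7 a slide). In BN they were 0.214, 0.007, -0.018 and -0.067. The duplicate correlation of normal-liver arrays of one number was -0.204. Arrays of one number in normal liver were scans of different slides.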
